A study of Oryza sativa Indica Group with 96 samples.

How the data were processed

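Panicle RNA of rice variety IR64 was measured by RNA sequencing in 96 libraries, 64 of a time course of night heating and 32 of a gradient of night temperatures. Per the labels' protocols, total RNA was extracted with a column kit with a DNase step, poly(A) RNA was selected on oligo(dT) beads, and libraries were made with a kit that keeps the strand. Per the submitters' processing notes, reads were aligned with HISAT2 (version given as 2) and counted with HTSeq 0.6.0. The genome build, the annotation, the strand setting of the counting and any merging of sequencing runs are not given in the sources used here, so reads of overlapping genes or of near-identical copies may have been lost or assigned to either gene.

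The deposited values are raw counts per gene, whole numbers with no normalization, in 1 table per experiment. In 16 time course libraries over 99% of the deposited counts above 0 were even, as if each read had been counted 2 times. Control 14 h replicate 3 holds multiples of 0.5, as a mean of 2 columns would give, and was treated as a column of expected counts, which the authors deposited unrounded. These were rounded to whole numbers before the tests. The even-valued libraries were used as deposited, and 3 alternatives were added after seeing the data: dividing them by 2 (and multiplying the library with values in steps of 0.5 by 2), a batch term for being even-valued, and leaving them out. Control 14 h and WNT 10.5 h keep 1 library each when they are left out, and such a library is assumed to vary like those of the other groups. The even-valued libraries were also tested alone, where 4 times have at least 1 in each treatment.

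Total counts per library ran from 11 to 30 M (time course) and from 4.28 to 21.5 M (gradient), with 23596 to 28341 genes detected per library. The gene IDs of the files begin with 12 numbered prefixes or a prefix for unplaced genes. None of them was paired with a name in the reference table (assembly ASM3414082v1), so 0 IDs matched. For this reason the 10 gene lists fixed by ID and the 16 fixed by description, and the tests of these lists, could not be run.

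Libraries were grouped by the treatment and time in their labels before the data were examined, and the tests, the alternatives and the rule for named genes were also fixed then. Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, a filter on low counts by group, a trended dispersion, robust quasi-likelihood fits and the quasi-likelihood F test, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The time course fit had a mean for each of 16 groups, and WNT was compared with Control at each of 8 times, on average over the times, between night and day, and as a treatment by time interaction. Rhythms were fitted as a cosine and a sine of 24 h in each treatment over 56 libraries, without Dusk, whose hour the labels do not give. In the gradient, a slope per °C was fitted at Dawn and at Dusk over 4 night temperatures, and each temperature was compared with 24 °C in a fit with a mean for each of 8 groups. CPM were computed on TMM-scaled library sizes, and log2 CPM with a prior count of 2.

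Named genes were those with the largest changes in each direction past the threshold with a mean of at least 5 CPM over the libraries of the experiment, and for the average over times the same direction at 7 or more of the 8 times. For the interaction they were those with the smallest p. The rule also asked for an informative description. As no description was paired with these IDs, that condition could not be applied, and at most 2 genes per direction are printed.

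Same-numbered Control and WNT libraries were checked for deviating together from their group means. All 4 pairs had a correlation above 0.1 at 3.5 h (0.32 to 0.406) and at none of the 7 other times, and nothing in the labels pairs them, so at 3.5 h the count with the replicate number as a block is given beside the other. Alternatives fixed beforehand were the DESeq2 1.42.0 test, DESeq2 size factors in edgeR, no filter, a stricter filter of 1 CPM in 4 libraries, a replicate block, only the compared groups in the fit, counts summed over times, Dusk at an assumed 12 h, and leaving out each library in turn. After seeing the data, the main axis of variation within groups was added as a covariate. It is the first singular vector of the deviations of log2 CPM from the group means, and each library's score on it keeps any difference between groups. An earlier form of this term, made independent of the groups, was tried first and dropped, because such a term narrows the error and cannot remove a difference along the axis from a comparison. Gene sets were tested with fry in limma 3.58.1, which asks whether the genes of a set move, on balance, in a single direction.

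The set of 60 co-varying genes was found on deviations from the group means, among 1999 genes with a standard deviation above 1 (log2), by average linkage joined at a correlation of 0.5. Among the 4 largest clusters it was the one with the lowest WNT against Control difference. Of 3 minimums tried for the standard deviation, the other two gave 36 and 22 genes, all of them members of the set. All these choices were made after seeing the data.

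The comparisons named here were tested on simulated counts with 200 changed genes, drawn from the means and library sizes of the real ones. Each gene was drawn independently of the others, so the simulated libraries lack the main axis of variation of the real ones. The shares recovered below may thus differ from those in the real data. In the comparison at Dawn over 23566 genes, edgeR recovered 15% of genes changed by a log2 of 1 and 90% of those changed by 2. It recovered 100% of both for the average over times, 4% and 73% for the interaction, and 44% and 98% for night against day. Rhythms in Control of amplitude 0.5 and 1 were recovered in 40% and 98% of genes, and differences in rhythm of these sizes in 9% and 83%. Over the 21689 genes of the gradient it recovered 24% and 76% for a slope at Dawn and 16% and 83% for a slope at Dusk that adds up to a log2 of 1 or 2 over the temperatures, 4% and 50% for a difference in slopes, and 18% and 75% for 30 against 24 °C at Dawn. Most simulated changes of a log2 of 1 at Dawn were thus missed, although most genes called at Dawn in the real data changed by less (51 of 181 rose by more than 1 and 45 of 242 fell below -1), and the 7 other times were not simulated.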

Results

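RNA was measured in panicles of field-grown rice, variety IR64, an indica rice bred in the Philippines and widely used as a reference for tropical irrigated rice. The panicle is the branched flowering head that carries the spikelets, and it was harvested during flowering. In a time course, plants heated with an infrared heater at night (labelled WNT) were compared with unheated plants (Control) at 8 times of day: Dawn, 3.5, 7 and 10.5 h after dawn, Dusk, and 14, 17.5 and 23 h after dawn. Each treatment had 4 replicate libraries at each time, 64 libraries in all. In a temperature gradient, plants under field tents were kept at night temperatures of 24, 26, 28 or 30 °C and sampled at Dawn and at Dusk, with 4 replicate libraries per group and 32 libraries in all. No label says that the replicates came from separate plots or tents, so p-values measure only the spread between these samples, which may in part be technical.

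The count tables listed 57174 genes. Total counts per library, in mega (M) counts, ran from 11 to 30 M in the time course and from 4.28 to 21.5 M in the gradient. In 16 of the 64 time course libraries over 99% of the counts above 0 were even numbers, and in Control 14 h replicate 3 the values were multiples of 0.5, with 25.5% of them not whole. If each read was counted 2 times in the even-valued libraries, their depth was 6.24 to 10.9 M. No pair of libraries within a group agreed within sampling noise: the lowest chi-square per degree of freedom among 144 such pairs was 6.66. After the filter on low counts, 23566 genes were tested in the time course and 21689 in the gradient. The gene IDs of the files were paired with no gene name in the reference table, so genes are given by ID, at most 2 that rose and 2 that fell per comparison, and none is described by function.

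The first question was how warmer nights changed the panicle transcriptome on average over the day. Averaged over the 8 times, 1024 genes were higher and 1349 lower in WNT than in Control, 2373 of 23566 in all (edgeR quasi-likelihood test, adjusted p 0.05). Most changes were small: the median log2 change was 0.26 among genes that rose and -0.33 among genes that fell, while 24 genes rose by more than 1 and 202 had a log2 change below -1. MH11t0409200 fell by 3.68 on the log2 scale (SE 0.49, adjusted p = 1.82e-06), from 304 ± 460 CPM (counts scaled to library size) in Control to 15.2 ± 10.7 in WNT (SD, n = 32 each). MH12t0198800 fell by 3.64 (SE 0.50, adjusted p = 2.38e-06), from 243 ± 384 to 11 ± 6.31 CPM. Among the genes that rose, MH04t0315800 changed by 1.20 (SE 0.17, adjusted p = 4.31e-06), from 13.6 ± 25.3 to 55.2 ± 97.8 CPM. MH06t0274400 changed by 1.23 (SE 0.40, adjusted p = 0.0366), from 3.33 ± 3.45 to 7.11 ± 5.12 CPM. These log2 changes are means of the differences at the 8 times. The CPM means and SDs are over the libraries of all times together, so their ratio need not match the log2 change.

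In a set of 60 genes, levels moved together from library to library within groups. Of the 202 genes with a mean log2 change below -1, 56 belonged to this set, MH11t0409200 and MH12t0198800 among them, but the set was picked from the 4 largest clusters for its low WNT level, so this share follows in part from the choice. The mean log2 CPM of the set was 1.82 ± 1.84 in Control and 0.32 ± 0.41 in WNT (SD, n = 32 each), and 13 of the 32 Control libraries lay above the highest WNT library, at 1.32. The difference was -1.51 (permutation test within times, two-sided, 100000 resamples, p = 1e-05, the smallest they can give). The set was first noticed through this difference, so its p is not independent evidence. Control levels of the set varied with time. At 17.5 h Control libraries stood at 2.26 to 4.86 and WNT libraries at 0.216 to 1.32. At 10.5 h Control libraries stood at 0.203 to 0.754, below the highest WNT library of all times.

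**Figure D1:**
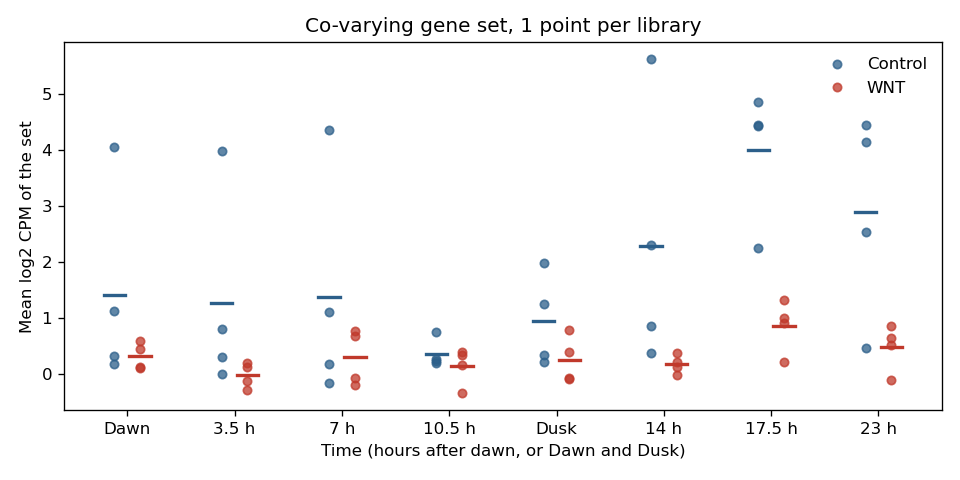
Mean log2 CPM of the set of 60 co-varying genes on the y axis, by time of sampling on the x axis, with 1 point per library and a bar at each group mean (n = 4). Control points reach 5.62 and spread widely within most times, while no WNT point lies above 1.32.

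The count of genes changed on average depended on the libraries and the model. Summing counts over the times, given first, changes the replicate unit and also the weight of each time. With counts summed over the times for each replicate number, 4 Control against 4 WNT sums, 189 genes passed (52 higher, 137 lower), and with the even-valued libraries left out 838 passed (281 higher, 557 lower). With the axis of variation shared by all groups as a covariate, an alternative chosen after seeing the data, 4401 passed, with the balance turned (2341 higher, 2060 lower). Without the even-valued libraries MH11t0409200 fell by 2.32 (adjusted p = 0.00302) and MH12t0198800 by 2.14 (adjusted p = 0.00513). MH06t0274400 and MH04t0315800 did not pass on the summed counts, with log2 changes of 1.08 and 1.96 (adjusted p = 0.252 and 0.0851 in edgeR), and MH06t0274400 lost its call in 15 of 74 alternatives, with adjusted p up to 0.252 and log2 changes of 1.08 to 1.48.

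At Dawn, the end of the heated night, 181 genes were higher and 242 lower in WNT. MH07t0091500 stood at 36.1 ± 24.2 CPM in Control and 183 ± 69.2 in WNT (SD, n = 4 each), a log2 change of 2.34 (SE 0.59, edgeR adjusted p = 0.0269), with all 4 WNT libraries above all 4 Control libraries. MH03t0660400 changed by 2.13 (SE 0.46, adjusted p = 0.0103), but its WNT libraries ran from 8.1 to 141 CPM and the 4 Control libraries from 10 to 15.8. MH05t0326000 fell by 3.74 (SE 0.74, adjusted p = 0.00463), from 112 ± 116 to 8.27 ± 10.4 CPM. MH03t0738500 fell by 2.76 (SE 0.67, adjusted p = 0.022), from 5.06 ± 2.62 to 0.75 ± 0.36 CPM, with no overlap between the groups. Among all genes called at Dawn the median log2 change was 0.84 for those that rose and -0.62 for those that fell.

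The number at Dawn moved with most single libraries and rested on no one of them. It was 108, 169, 159 and 1381 without Control Dawn replicates 1, 2, 3 and 4, and 175, 576, 126 and 119 without WNT Dawn replicates 1, 2, 3 and 4. Where it fell, 2837 to 3371 genes had an unadjusted p under 0.05, against 3579 with all libraries. The number called at Dawn was 936 with DESeq2, 2 with only the Dawn libraries in the fit, 61 without the even-valued libraries and 1551 with the shared axis as a covariate, with the balance turned (951 higher, 600 lower). Without WNT Dawn replicate 1, MH03t0660400 changed by 0.92 (adjusted p = 0.264). Each of the 4 named genes lost its call with only the Dawn libraries in the fit (adjusted p 0.287 to 0.408), where the log2 changes of MH07t0091500, MH03t0660400, MH05t0326000 and MH03t0738500 were 2.35, 2.13, -3.74 and -2.74, and without the even-valued libraries (adjusted p 0.0743 to 0.236), where they were 1.95, 2.21, -2.5 and -2.96. MH07t0091500 also lost its call without Control replicate 1, 2 or 3 or WNT replicate 3 or 4 (log2 2.08 to 2.4), and MH03t0738500 without Control replicate 1 or 2 or WNT replicate 1 or 3 (log2 -2.46 to -2.68), so these changes stayed about as large.

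At 3.5 h after dawn 52 genes were higher and 56 lower in WNT, with median log2 changes of 1.00 and -1.30. At 7 h 42 were higher and 26 lower, with medians of 0.81 and -1.15. Dawn and 3.5 h shared 4 genes that rose and 3 that fell, against 0.399 and 0.575 for independent lists, and no gene moved in opposite directions. At 17.5 h 1 gene rose and 5 fell, and at 23 h 5 fell. At 10.5 h, Dusk and 14 h edgeR called 0 genes, with 1091, 993 and 1233 genes at an unadjusted p under 0.05, while DESeq2 called 10, 0 and 34. In all, 595 genes passed at 1 or more of the 8 times.

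**Figure D2:**
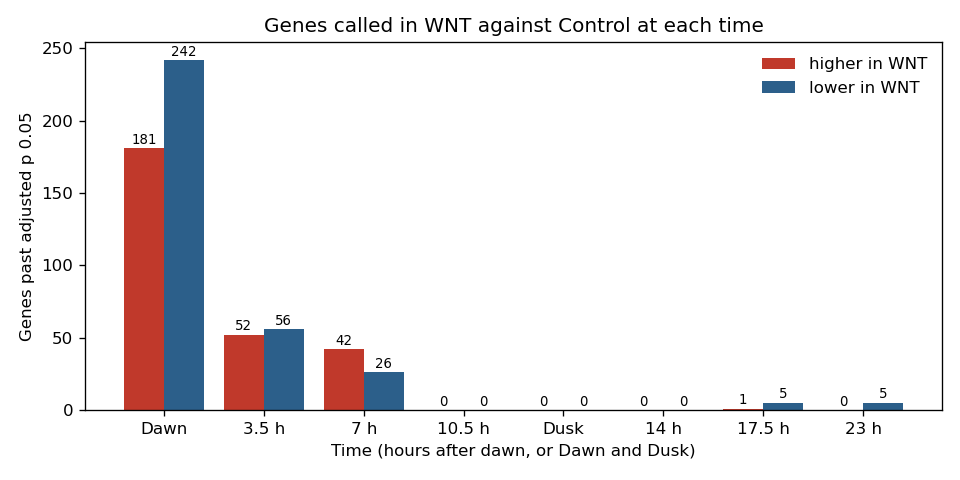
Number of genes past adjusted p 0.05 in WNT against Control on the y axis, by time of sampling on the x axis, with genes higher and lower in WNT as separate bars. The bars are tallest at Dawn (181 and 242) and stand at 0 at 10.5 h, Dusk and 14 h.

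At 3.5 h, where same-numbered libraries of the treatments deviated together, 184 genes passed with the replicate number as a block. The counts at these times also moved with single libraries. At 3.5 h the count was 51, 31, 6 and 329 without Control replicates 1, 2, 3 and 4, and 47 and 34 without WNT replicates 1 and 4. At 7 h it was 16, 25 and 1 without Control replicates 1, 2 and 3, and 16 and 316 without WNT replicates 1 and 3. At 17.5 h it was 2, 0 and 106 without Control replicates 1, 2 and 4, and 0, 2 and 0 without WNT replicates 2, 3 and 4. At 23 h it was 1, 3, 12 and 0 without Control replicates 1 to 4, and 23, 33, 0 and 1 without WNT replicates 1 to 4. At 10.5 h it was 1 without Control replicate 2. DESeq2 called 503 genes at 3.5 h, 464 at 7 h, 166 at 17.5 h and 202 at 23 h, while with only the libraries of that time in the fit edgeR called 0 at each of the 4 times, with 2996, 2479, 3732 and 1427 genes at an unadjusted p under 0.05.

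Whether the heating acted differently over the day was tested as a treatment by time interaction, which 19 genes passed. MH03t0160700 changed strongly over the sampled times: in Control it rose from 2.8 ± 0.81 CPM at Dawn to 317 ± 42.9 at 10.5 h and fell back to 3.51 ± 1.6 at 23 h (SD, n = 4). Its levels in WNT were close to these at 7 of the 8 times, with log2 differences between -0.15 and 0.24, but at 3.5 h it stood at 9.57 ± 4.35 in Control and 2.12 ± 0.57 in WNT. That difference was -2.18 (SE 0.26, edgeR adjusted p = 6.37e-07), and the interaction had an adjusted p of 0.0026. In Control the gene stood at 123 ± 35.9 CPM by 7 h, so 3.5 h lies on a steep rise. A different hour of sampling at 3.5 h was not tested and cannot be told apart from an effect of heating. MH04t0406200 was higher in WNT at Dawn, 15.5 ± 1.92 against 6.36 ± 1.84 CPM (log2 1.28, SE 0.24, adjusted p = 0.00244), with an interaction adjusted p of 0.0185. At 17.5 h its difference was -0.81 (SE 0.24, adjusted p = 0.164).

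**Figure D3:**
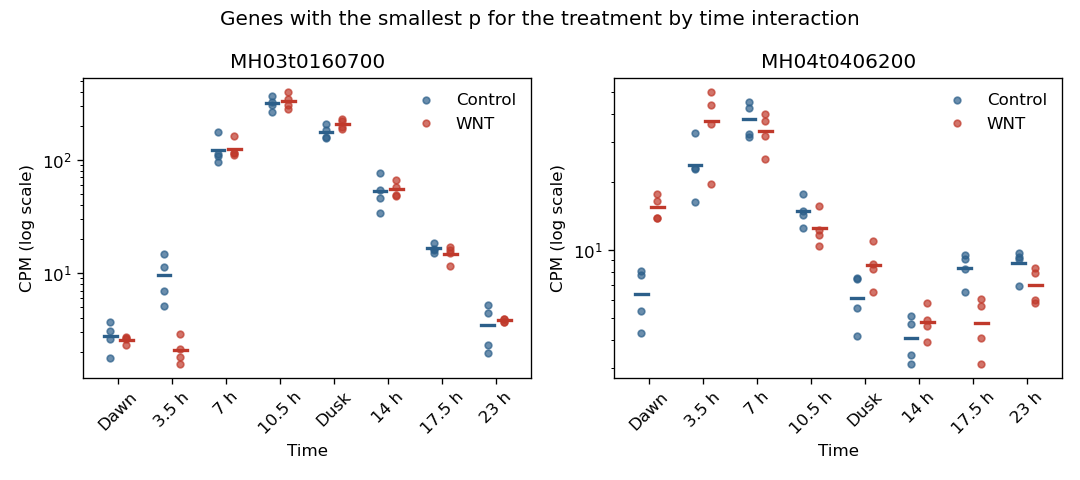
CPM on a log scale on the y axis, by time of sampling on the x axis, for MH03t0160700 (left) and MH04t0406200 (right), with 1 point per library and a bar at each group mean (n = 4). At 3.5 h the 4 WNT points of MH03t0160700 lie below the 4 Control points, and at Dawn the 4 WNT points of MH04t0406200 lie above them.

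The interaction of MH03t0160700 passed in all 74 alternatives tried, with adjusted p up to 0.0345, and that of MH04t0406200 in all but that without the even-valued libraries (adjusted p = 0.104). The count of 19 was 4 without a filter on low counts, 5 without the even-valued libraries, 30 with the stricter filter, 33 with a replicate block, 42 with treatment and number together as 8 blocks, 565 with the DESeq2 likelihood ratio test and 760 with the shared axis as a covariate. Leaving out Control Dawn replicates 1, 2 and 4 gave 6, 12 and 87, WNT Dawn replicate 2 gave 38, Control 3.5 h replicates 2, 3 and 4 gave 12, 12 and 39, and Control Dusk replicate 1 gave 36. WNT 14 h replicate 4 gave 30, Control 17.5 h replicates 2 and 4 gave 12 and 54, and WNT 23 h replicates 1 and 2 gave 30 and 40. A contrast of the WNT effect at night (14, 17.5 and 23 h) with that by day (3.5, 7 and 10.5 h) gave 0 genes with edgeR, with 1273 at an unadjusted p under 0.05 and 1 with DESeq2, and 1 without WNT 23 h replicate 4.

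Many genes fitted a 24 h rhythm in both treatments. The times ran from Dawn to 23 h after dawn, with no repeated cycle. A difference between times that does not repeat daily can thus not be told apart from a rhythm. A 24 h rhythm was called in 10342 genes in Control and 12029 in WNT, 43.9% and 51% of those tested, and 8189 genes were called in both. Of the genes rhythmic in Control, 79.2% were also called in WNT. Fitted peaks fell most often between 8 and 12 h after dawn in Control (2336 genes, 22.6%) and between 20 and 24 h in WNT (2869 genes, 23.9%). The next largest bin was 20 to 24 h in Control (2066 genes, 20%) and 8 to 12 h in WNT (2463 genes, 20.5%), so the same bins led in both. Among genes called in both, the median peak was -0.27 h in WNT relative to Control, and 85.7% of peaks lay within 2 h of each other. The median amplitude was 0.43 in Control and 0.50 in WNT on the log2 scale. The test of the difference in rhythm called 0 genes with edgeR, with 1996 at an unadjusted p under 0.05 and 1 with DESeq2, so a gene that is in only one of the lists is not thereby shown to differ between the treatments.

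**Figure D4:**
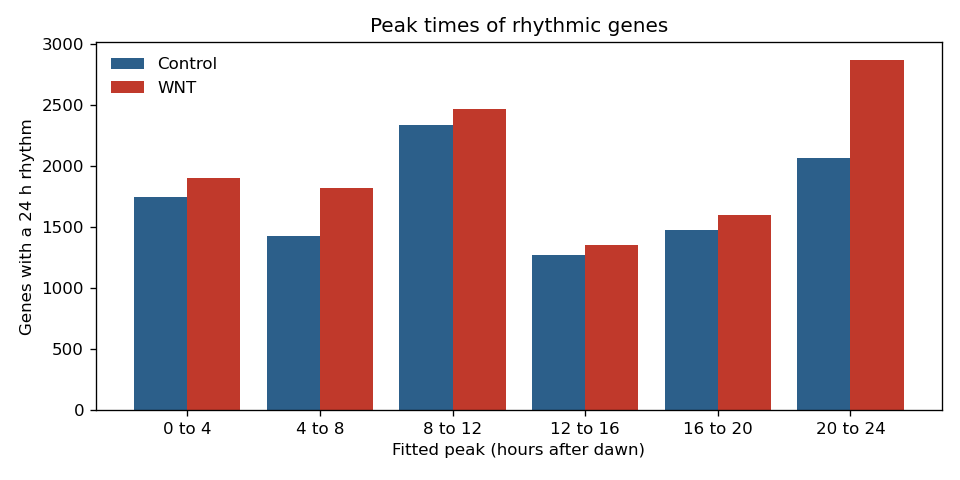
Number of genes with a 24 h rhythm on the y axis, by fitted peak time in bins of 4 h after dawn on the x axis, for Control and WNT. Bars are tallest at 8 to 12 h in Control (2336 genes) and at 20 to 24 h in WNT (2869 genes). The next tallest are at 20 to 24 h in Control (2066 genes) and at 8 to 12 h in WNT (2463 genes).

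Dusk had no hour in the labels and was left out of the rhythm fit, which used 56 libraries. The difference in rhythm called 41 genes without the even-valued libraries, 20 without a filter on low counts and 6 with the shared axis as a covariate, and between 0 and 3 when single libraries were left out, the most without WNT 17.5 h replicate 3.

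The tents asked how expression moved over the range from 24 to 30 °C at night. At Dawn, 1 gene rose and 10 fell with temperature (slope over 4 temperatures, 16 libraries of that time in a fit of 32). MH01t0191500 fell by 0.85 log2 per °C (SE 0.12, edgeR adjusted p = 0.000611), and its mean level was 55.7 ± 20.3 CPM at 24 °C, 50.4 ± 25.4 at 26 °C, 9.84 ± 9.94 at 28 °C and 1.99 ± 0.71 at 30 °C (SD, n = 4 each). MH12t0424100 fell by 0.54 per °C (SE 0.09, adjusted p = 0.00578), from 27.7 ± 13.6 CPM at 24 °C to 3.52 ± 0.74 at 30 °C. MH06t0698300, the gene that rose, changed by 0.23 per °C (SE 0.04, adjusted p = 0.0166), from 13.7 ± 1.55 to 38 ± 12 CPM. Against 24 °C, edgeR called 0 genes at 26 °C (1288 at an unadjusted p under 0.05, 316 with DESeq2), 1 at 28 °C and 10 at 30 °C, of which 2 rose and 8 fell. Of the 10, 9 were also among the 11 genes with a slope.

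Each of the 3 named genes lost its call with only the Dawn libraries in the fit (adjusted p 0.154 to 0.512, with 0 genes called by edgeR and 748 at an unadjusted p under 0.05), although the slopes of MH01t0191500, MH12t0424100 and MH06t0698300 hardly moved there (-0.848, -0.542 and 0.226 per °C). MH06t0698300 also lost it without any single 24 °C replicate or 30 °C replicate 1, 2 or 3, with slopes of 0.211 to 0.23 and adjusted p of 0.0523 to 0.104. The count of slopes was 64 without 30 °C Dawn replicate 4, where most rose (44 rose, 20 fell), 36 with DESeq2 (18 rose, 18 fell), 13 with DESeq2 size factors (3 rose, 10 fell), 27 without a filter and 24 with the shared axis as a covariate. The 30 against 24 °C count was 4, 6 and 137 without 24 °C replicates 1, 3 and 4, and 4, 4 and 37 without 30 °C replicates 1, 2 and 4, of the 37 again most rose (25 rose, 12 fell). Its balance turned with the method: DESeq2 called 478 genes, of which 416 rose, and edgeR on those 8 libraries alone called 359, of which 350 rose. The 26 °C count was 3 and 1 without 26 °C replicates 2 and 3. The 28 °C count was 2 without 24 °C replicate 2 and 0 without any of the other 24 °C replicates or 28 °C replicate 1, 2 or 4.

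At Dusk 9 genes rose with night temperature and none fell (edgeR, 1379 at an unadjusted p under 0.05 in both directions, 52 with DESeq2, all 52 rising). MH08t0108500 changed by 1.07 log2 per °C (SE 0.14, adjusted p = 0.000202) and MH04t0124000 by 0.77 (SE 0.14, adjusted p = 0.0271). Both were low at this time and stood out in 1 library: at 30 °C MH08t0108500 was at 8.64 CPM in replicate 2 and 0.23 to 1.01 in the others, and MH04t0124000 at 27.1 in replicate 2 and 0.67 to 2.07 in the others. At 24 °C MH08t0108500 was at 0 in 3 libraries and at 0.0529 CPM in the other. Against 24 °C, edgeR called 0 genes at 26 °C and 0 at 28 °C (708 and 1019 at an unadjusted p under 0.05, 10 and 11 with DESeq2), and 1 that rose at 30 °C (52 with DESeq2).

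Without 30 °C Dusk replicate 2 no gene had a slope at Dusk (MH08t0108500 0.632 per °C, adjusted p = 0.22, MH04t0124000 0.35 per °C, adjusted p = 0.57), and with only the Dusk libraries in the fit 0 did in edgeR, with 2043 at an unadjusted p under 0.05. The count was 3 and 3 without 24 °C replicates 1 and 2, 4 and 4 without 26 °C replicates 2 and 3, 14 without 28 °C replicate 1 and 19 without 30 °C replicate 3. MH04t0124000 also lost its call without any single 24 °C replicate or 26 °C replicate 2 or 3 (0.754 to 0.837 per °C, adjusted p 0.0509 to 0.0719), with a replicate block (0.73 per °C, adjusted p = 0.236) and with only the Dusk libraries in the fit (0.77 per °C, adjusted p = 0.437). With the replicate block 3 genes had a slope at Dusk. The 30 °C count was 3 without 30 °C replicate 1 and 0 without 30 °C replicate 2 or any single 24 °C replicate, with a replicate block or with only the 2 compared groups in the fit. The slopes at Dusk and Dawn differed in 9 genes, all with the higher slope at Dusk. Only 2 of these were among the 9 genes with a slope at Dusk. For the other genes with a slope at Dusk, no difference from Dawn was called. The count of differing slopes was 26 with DESeq2, 20 with the shared axis as a covariate, 15 without 24 °C Dawn replicate 2, 17 without 30 °C Dawn replicate 4, 15 without 30 °C Dusk replicate 1 and 3 without 30 °C Dusk replicate 2.

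The 2 experiments warmed the night in different ways, and their effects were compared across the 21409 genes tested in both. At Dawn 0 genes were called both in WNT against Control and in the temperature slope, where independent lists would share 0.196, and at Dusk WNT against Control called none to compare. Of the genes called in WNT at Dawn 30.3% had a slope of the same sign. No share over all genes stands beside this one, so it cannot be read as particular to the called genes. Across genes, which are not independent replicates, the WNT difference and the slope had Pearson's r = -0.195 and Spearman's rho = -0.232 at Dawn, and r = 0.367 and rho = 0.219 at Dusk. At Dawn r was 0.0609 without the libraries of replicate number 3 and 0.185 with the shared axis as a covariate. At Dusk it stayed positive without any single replicate number, between 0.202 and 0.525, and was 0.16 with the shared axis as a covariate.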

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

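The tests of the co-varying set, of the shared axis and of the calls at Dawn with the axis as a covariate were chosen only after these results were seen, while the test of the hour of sampling at Dawn was written down before its result was seen. Of 108 groups of 4 libraries checked for a library far from the others, 9 had one, where chance gives about 5%.

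In WNT at 23 h replicate 2 had a total count of 21.9 M, against 12.5 to 13.3 M in the other libraries, and it is one of the even-valued libraries. MH05t0326000 stood at 23.9 CPM in WNT Dawn replicate 2 and at 3 to 3.18 CPM in the other WNT Dawn libraries. MH03t0160700 stood at 163 CPM in the highest WNT 7 h library and at 111 to 115 in the others. In 30 °C Dusk replicate 2, MH08t0108500 stood at 8.64 CPM against 0.23 to 1.01 in the others, and MH04t0124000 at 27.1 CPM against 0.67 to 2.07. In the 24 °C Dusk libraries MH08t0108500 stood at 0.0529 CPM in replicate 2 and at 0 in the others. For the co-varying set, mean log2 CPM was 0.754 in Control 10.5 h replicate 3 against 0.20 to 0.28 in the others, 2.26 in Control 17.5 h replicate 4 against 4.43 to 4.86, and 3.24 in 30 °C Dawn replicate 2 against 2.27 to 2.39. A test of the difference itself called 19 genes for a WNT effect that differed between times. Such a test called 9 genes for a temperature slope that differed between Dusk and Dawn. The drawn relabellings described below do not exclude chance for either count.

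The set of 60 co-varying genes was high in some Control libraries and low in WNT, with 9 Control libraries more than 2 log2 above the Control median of 0.986. Doubled counts in the even-valued libraries cannot account for this, since 6 of these 9 libraries are not even-valued. Library size as deposited does not follow the set: over the 64 libraries, deviations of the set score and of log2 total count from their group means had r = -0.194 (permutation p = 0.224, adjusted 0.374) and rho = -0.0584 (p = 0.698), with r = -0.191 without the 2 libraries of the most unusual size, well below the size of 0.5 that this cause would need. These totals are not divided by 2 in the even-valued libraries, so they do not cover the depth if reads were counted 2 times there. An exchange of labels between Control and WNT stays open, since the set was chosen for being low in WNT and its scores cannot test this. The genes stood next to each other in the ID order far more often than random sets of 60 (15 neighbouring pairs against a mean of 0.0912 and at most 3 in 10000 draws), and an effect of the heating, which the design names, stays open as a hypothesis, as do material of another tissue and a difference in stage, which were not tested for want of gene names.

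Within groups, libraries differed along a single axis that held 46.2% of the variance of log2 CPM in the time course and 39.1% in the gradient, and the gene loadings of the 2 axes had a correlation of 0.612 in size. Library size as deposited does not follow the axis over the 64 libraries (r = -0.000213, permutation p = 0.999, adjusted 0.999; rho = -0.0397, p = 0.778; r = -0.0206 without the 2 farthest libraries). Being even-valued does not either (r = 0.027, p = 0.849, adjusted 0.999; rho = -0.00729, p = 0.956; r = -0.00829 without the 2 farthest). The share of counts in the 10 most abundant genes had r = 0.284 (p = 0.0522, adjusted 0.13 over 5 relations) and rho = 0.302 (p = 0.0341), with r = 0.312 without the 2 farthest, too weak to be the whole source of the axis. The TMM factor, computed from the same counts, followed the axis closely (r = -0.861, rho = -0.869, p = 1e-05 for each, the smallest the resamples can give, adjusted 5e-05; r = -0.852 without the 2 farthest) in the time course but not in the gradient (r = -0.0733), so in the time course the axis goes with the composition of the libraries. With each library centred at its median gene the axis held 46.1% of the variance and had a correlation of 1 with the first, but the scaling already centres the typical gene, so this does not test an error of scaling, which stays open. What makes the composition differ stays open: no biological explanation was tested, and RNA quality, stage and the mix of panicle tissues were not tested either.

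More genes were called at Dawn than at the other times: 423, against 108 at most elsewhere, and whether Dawn itself differs from each other time in this count was not tested. The order depended on the libraries and the threshold: without the even-valued libraries Dawn had 61 genes, 3.5 h 448 and 17.5 h 131, and at an unadjusted p under 0.05 3.5 h had 3947 genes and Dawn 3579. The shared axis does not explain these calls, since 100% of the 423 genes were called again in the same direction with the axis as a covariate, with a median absolute log2 change of 0.733 without and 0.725 with the covariate. A Dawn harvest at a slightly different hour in the WNT plants cannot be told apart from an effect of heating. Of the 423 genes, 73% had a WNT difference with the sign of their Control change from 23 h to 3.5 h, between the 80% set beforehand for a shift in hour and the 65% set against it. An effect of the heated night, the biological explanation that the design names, stays open beside it. Chance stays open too, as 4 of 35 splits of the Dawn libraries, the real one included, gave 423 or more genes (highest other 2792).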

How the results depend on the processing

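The alternatives with the even-valued libraries and with the shared axis were chosen after seeing the data, and the others were fixed beforehand. The rhythm counts in Control and WNT and the sign of the Dusk correlation between the experiments stayed within 1.5 times, or on the same side of 0, under every alternative run. The tests of gene lists, leaving out marker lists and the options of these tests were not run, since no ID was paired with a name, and the pseudocount options were not run because the values are counts. At Dawn few of the simulated genes changed by a log2 of 1 passed, and the other single times were not simulated. The causes of the shifts were not tested, except where fewer libraries entered by construction.

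With the DESeq2 test, the WNT counts were 936 at Dawn (386 higher), 503 at 3.5 h, 464 at 7 h, 10 at 10.5 h, 34 at 14 h (3 higher), 166 at 17.5 h (11 higher) and 202 at 23 h (36 higher), 565 for the interaction, 1 for night against day and 1 for the rhythm difference. In the gradient it called 36 slopes at Dawn, 52 at Dusk, 26 differences in slope, 316, 15 and 478 genes at 26, 28 and 30 °C at Dawn, and 10, 11 and 52 at Dusk. DESeq2 size factors in edgeR gave 0 at 28 °C at Dawn, changed no other count by more than 1.5 times, and gave 5 calls at 17.5 h, all lower, 7 at 23 h (1 higher) and 13 slopes at Dawn (3 rose).

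With only the compared groups in the fit, the counts were 2 at Dawn and 0 at 3.5 h, 7 h, 17.5 h and 23 h, 0 slopes at Dawn and 0 at Dusk, 0 and 359 genes at 28 and 30 °C at Dawn, and 7 and 0 at 28 and 30 °C at Dusk. With no filter, the counts were 63 at 3.5 h, 35 at 7 h, 3 at 17.5 h, 2 at 23 h, 4 for the interaction, 20 for the rhythm difference and 27 slopes at Dawn (16 rose). The stricter filter gave 30 for the interaction and 0 at 28 °C at Dawn. Counts summed over times gave 189 for the average.

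Same-numbered Control and WNT libraries had correlations of deviations above 0.1 in 16 of 32 pairs (-0.665 to 0.719), in all 4 pairs only at 3.5 h, gradient libraries in 11 of 24, and 22 of 64 libraries were closest to their own number. With a replicate block the counts were 489 at Dawn, 184 at 3.5 h, 133 at 7 h, 4 at 17.5 h, 21 at 23 h, 2587 on average, 33 for the interaction, 3 slopes at Dusk and 0 at 30 °C at Dusk, and 42 for the interaction with treatment and number together as 8 blocks. The block moved no other count by more than 1.5 times, and of the named genes it ended the call of MH04t0124000 at Dusk (adjusted p = 0.236).

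Without the even-valued libraries the counts were 61 at Dawn, 448 at 3.5 h, 5 at 7 h (1 higher), 131 at 17.5 h, 59 at 23 h, 838 on average, 5 for the interaction and 41 for the rhythm difference. With only these libraries in the fit, 1 to 3 per group, edgeR called 0 at Dawn, 7 h, 10.5 h and 23 h and 0 on average over these 4 times (2066, 2007, 880, 1943 and 2407 at an unadjusted p under 0.05, 6 residual degrees of freedom; DESeq2 was not run on them), and so few libraries say nothing about the stability of the calls. With their counts divided by 2, 23 h gave 0, and with a batch term for them 7 h gave 110. With the shared axis as a covariate the counts were 1551 at Dawn (951 higher), 1099 at 7 h (707 lower, where without it most were higher), 2 at 10.5 h, 5 at 14 h, 20 at 17.5 h, 322 at 23 h, 4401 on average (2341 higher), 760 for the interaction, 6 for the rhythm difference, 24 slopes at Dawn, 37 at Dusk, 20 differences in slope, 0 and 20 at 28 and 30 °C at Dawn and 6 at 30 °C at Dusk. The correlation of the experiments at Dawn was 0.185 there, reversed from -0.195, and 0.16 at Dusk. At 3.5 h the count was 107, but only 63 of the 108 genes called without the axis were among them.

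Leaving out single libraries gave 108 (without Control replicate 1) to 1381 (without Control replicate 4) at Dawn, 6 (Control replicate 3) to 329 (Control replicate 4) at 3.5 h, 1 (Control replicate 3) to 316 (WNT replicate 3) at 7 h, 0 to 1 (Control replicate 2) at 10.5 h, 0 to 106 (Control replicate 4) at 17.5 h, 0 to 33 (WNT replicate 2) at 23 h and 0 at Dusk and 14 h. The average ran from 2074 to 2797, the interaction from 6 (Control Dawn replicate 1) to 87 (Control Dawn replicate 4), night against day from 0 to 1, the rhythms from 9838 to 10697 in Control and 11512 to 12343 in WNT, and their difference from 0 to 3 (WNT 17.5 h replicate 3). Slopes ran from 9 to 64 (30 °C replicate 4) at Dawn, from 0 (30 °C replicate 2) to 19 (30 °C replicate 3) at Dusk, and their difference from 3 to 17. Against 24 °C at Dawn the ranges were 0 to 3 at 26 °C, 0 to 2 at 28 °C and 4 to 137 (24 °C replicate 4) at 30 °C, and at Dusk 0, 0 and 0 to 3. The correlation of the experiments without a replicate number ran from -0.411 to 0.0609 at Dawn, reversed without number 3, and from 0.202 to 0.525 at Dusk.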

Other observations

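The tests of the genes called at Dawn at other times, of the shift in peak time and of the splits with the shared axis as a covariate were chosen only after the results were seen, while the splits of the main comparisons, those with replicate numbers kept together, with summed counts and with the replicate block, and the tests of the Dusk and Dawn genes of the 24 °C plants were written down before their results were seen.

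Panicles differed widely between Dusk and Dawn in both experiments. In Control 5163 genes differed, 2599 of them higher at Dusk, and at 24 °C 2501 differed, 1103 of them higher at Dusk. The Dusk against Dawn changes had r = 0.695 and rho = 0.58 across genes, which are not independent replicates, and of the 1876 genes called in both experiments 99.8% had the same sign. No library is shared by the 2 comparisons.

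A hypothesis was that the heater moves the genes that differ between Dusk and Dawn. The sets of genes higher at Dusk (1099) and at Dawn (1387) in the 24 °C plants were tested in WNT against Control at each time and on average, and the smallest adjusted p of 18 fry tests was 0.288, with unadjusted p as low as 0.0305 at 14 h. No passing test was the bound written beforehand against the hypothesis. With treatment relabelled within times in 12 draws and a shift put on the counts of both sets, in opposite directions, 90.6% of tests at single times and 24 of 24 on average passed at a log2 shift of 0.25, and 13.5% and 20 of 24 at 0.1. A common shift of these sets by 0.25 at all times together is thus argued against. A shift at only some of the times was not simulated and stays open. A smaller one at single times, or a move of their genes in both directions, stays open too.

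A second hypothesis was that the changes at Dawn last beyond Dawn. Of 14 fry tests of the 181 genes that rose and the 242 that fell at the 7 other times, 1 passed in the direction of Dawn, that of the genes that fell at 23 h (adjusted p = 0.0291, median log2 change -0.22, 85.1% of genes in that direction), and 6 had an unadjusted p under 0.05. The genes that fell at Dawn may thus be lower already at 23 h, while for the other times the tests leave the question open.

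Another hypothesis was that heating moves the phase of the daily rhythm. Over 14776 genes rhythmic in a fit without treatment, the median peak shift was -0.258 h in WNT, and 6 of 100 relabellings of treatment within times gave a shift as large, up to 0.472 h. The median log2 ratio of amplitudes was 0.10, with 16 of 100 relabellings as far from 0. An earlier phase in WNT cannot be told apart from chance with these libraries.

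Other splits of the same libraries were tested, all 35 splits of 8 libraries at the single times and drawn relabellings, fewer than the design allows, for the rest. At 7 h 1 of 35 gave 68 genes (highest other 12) and at 17.5 h 1 of 35 gave 6 (highest other 3). This is the smallest share that 35 splits can give, and it was not adjusted over the comparisons. Single libraries also moved these counts, to 1 at 7 h without Control replicate 3 and to 0 at 17.5 h without Control replicate 2. Chance is thus less likely there but not excluded. At Dawn 4 of 35 splits gave 423 or more, the highest other 2792, so chance cannot be excluded, and a split with several times the real count points to a structure of the samples. At 23 h 3 of 35 gave 5 or more (highest other 10), so chance cannot be excluded. At 10.5 h, Dusk and 14 h the real count was 0 (highest others 2, 7 and 2), which all 35 splits reach whatever the labels, so the splits say nothing there. At 3.5 h only the real split, 1 of 35, gave as many as 108 (highest other 54), but same-numbered libraries deviated together there, which these splits ignore. Only 8 splits part all 4 pairs, too few for a share under 0.05: the real one gave 108 (highest other 10) and, with the replicate block, 184 (1 of 8, highest other 10).

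Over 60 drawn relabellings within times, the average over times gave 2373 only in the real one (1 of 60, highest other 25). This would exclude chance only if the libraries of different times were independent. If a replicate number marks the same plot at all times, which the labels do not say, whole series of a treatment and a number have to be exchanged. Then 2 of 35 splits gave 2373 or more, the highest other 3475, and 15 other splits gave calls. Counts this far above the 25 of the free relabellings argue against independence between times. Chance can thus not be excluded for the count of 2373. With counts summed over the times for each series, only the real split, 1 of 35, gave 189 (highest other 1), which makes chance unlikely for these. The interaction count of 19 was reached in 2 of 60, a share under 0.05, but so few draws give this share imprecisely. The highest other gave 615, which again points to a structure of the samples. Chance is thus not excluded by these draws. With numbers kept together 1 of 35 reached 19 (highest other 7), the smallest share these splits can give, which makes chance less likely there. The night against day count of 0 is reached in 60 of 60 by any labels (highest other 1), so it says nothing about chance. Shuffling times gave at most 5 rhythmic genes in Control (1 of 60 as many as 10342) and 32 in WNT (1 of 60 as many as 12029). Chance can be excluded for both as differences between times. The shuffling cannot tell a daily rhythm from a difference that does not repeat. The rhythm difference of 0 genes is likewise reached in 60 of 60 (highest other 16), which says nothing about chance.

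With the shared axis as a covariate, 1 of 35 splits gave as many genes as the real one at Dawn (1551, highest other 728), 7 h (1099, highest other 275), 14 h (5, highest other 2) and 23 h (322, highest other 258). Other splits also gave calls in this fit, 16 of them at Dawn and 12 at 23 h. The fit was chosen after seeing the data, so these shares do not exclude chance. At 3.5 h 2 of 35 reached 107 (highest other 135), at 10.5 h 5 of 35 reached 2 (highest other 19), and at 17.5 h 2 of 35 reached 20 (highest other 24), so chance cannot be excluded. The average (4401, highest other 8) and the interaction (760, highest other 283) were reached in 1 of 45 drawn relabellings each. This would make chance less likely only if the libraries of different times were independent, which the splits without the axis argue against. With numbers kept together, 1 of 35 reached the average (highest other 1119) and 1 of 35 the interaction (highest other 10). As above, a fit chosen after seeing the data cannot exclude chance. The counts of 0 at Dusk (35 of 35, highest other 1) and for night against day (45 of 45, highest other 265) are reached by any labels and say nothing.

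In the gradient, 18 of 100 relabellings of temperature gave 11 or more slopes at Dawn, with up to 7605 genes, and 6 of 100 gave 9 or more differences in slope, with up to 1322, so chance cannot be excluded and the libraries hold a structure of their own. At Dusk only the real labels gave 9 slopes (1 of 100, highest other 1). That share is under 0.05, but 0 slopes were called without 30 °C Dusk replicate 2. The count thus rests on 1 library, and chance is not excluded. Lost calls are not lost slopes: without that library MH08t0108500 and MH04t0124000 still had slopes of 0.632 and 0.35 per °C, lower than with it. Against 24 °C at Dawn, 3 of 35 splits gave at least the 1 gene at 28 °C (highest other 4) and 8 of 35 the 10 genes at 30 °C (highest other 2744), so chance cannot be excluded. At Dusk, 1 of 35 gave the 1 gene at 30 °C (highest other 0), the smallest share these splits can give. The call of this gene ended without 30 °C Dusk replicate 2 or any single 24 °C replicate. It also ended with the replicate block (0 called) and with only the compared groups in the fit (0 called). Chance is thus not excluded for this count of 1 gene. The counts of 0 at 26 °C at Dawn (highest other 1) and at 26 and 28 °C at Dusk (highest other 0 in both) are reached by 35 of 35 splits each whatever the labels and say nothing about chance.

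The correlation of the WNT difference with the temperature slope was tested on mean log2 CPM over the 35 splits of the time course libraries. At Dawn the real value was -0.0918, and 31 of 35 splits lay as far from 0 (highest other 0.555). At Dusk it was 0.511, and 6 of 35 lay as far from 0 (highest other 0.548), so chance cannot be excluded at either time.

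In the gradient, 44 of the 60 genes of the co-varying set were tested, and their mean log2 CPM lay between 1.57 and 3.44 in all 32 libraries. These scores rest on fewer genes than those of the time course and are not on the same scale.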
